A study of Mus musculus with 12 samples.

How the data were processed

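The deposited intensity values come as 2 tables of the same 12 arrays. In the first, per the file headers, each probe has an average signal intensity, from which the authors had subtracted 1 background constant per array, with no normalisation between arrays. In the second, deposited as the series matrix, the intensities are unsubtracted, linear and not normalised between arrays. The tables differed on each array by 1 constant, with a largest deviation of 0.00502 to 0.00969. Each detection p-value was deposited by the authors beside its signal, per the file headers, and how it was computed is not given in the sources used here. Per the labels, total RNA was extracted with Trizol from fresh-frozen tissue and biotinylated cRNA was made with the Ambion MessageAmp kit. The scanner software is not given in the sources used here, so how bead signals were averaged and scaled before deposition stays unknown.

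The median of the matrix columns was 89.3 and 85.8 in muscle, 87.3 and 87.5 in bone marrow, 92.3, 91.8, 122 and 117 in leiomyosarcoma and 110.1, 114, 111 and 108 in osteosarcoma. Subtracted medians lay between 5.07 and 11.8, and the highest signals between 56191 and 65216.1. All columns matched the sample labels, and the groups and replicate numbers follow the labels.

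Of 45281 probes, 34885 had 1 gene symbol in the probe annotation, 18 had several and 10378 were not listed. Of the 34885 probes with 1 symbol, 34807 matched a gene identifier of the reference gene table (assembly GRCm38.p6), which was used for names and the order of neighbouring genes only. The build behind the array is not given in the sources used here, so no coordinates are given. A probe was kept if its detection p was under 0.05 on at least 2 arrays, which left 21383 probes, 18013 of them with a gene name. A gene with several probes, as 4323 of the 11754 genes had, was represented by the probe of the highest mean over all arrays. The 3370 detected probes without a name were left out of the tests.

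Subtracted signals were background-corrected and quantile-normalised with neqc of limma (version 3.58.1, R 4.3.3; offset 16) and taken to log2. Because negative control beads are not in the files, neqc inferred the background from the detection p-values. A limma model of 4 group means was fitted to all 12 arrays (8 residual and 3.634 prior degrees of freedom), so that groups of 2 share the estimate of spread with groups of 4. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. Standard errors are the moderated ones of that model. Genes that differ in both tumours had to pass in the same direction in all 4 contrasts of a tumour with a normal tissue. The 28 gene lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists, and again with an estimated correlation. The limma and camera tests were two-sided, while comparisons with the 95th percentile of random lists or of random 11-gene runs were one-sided.

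The comparisons, tests, thresholds, gene lists, the rule for named genes and the alternatives not marked otherwise were chosen before the data were examined. Named genes are the 7 measured genes of a fixed panel of the p53 pathway and cell cycle, the 6 largest rises and 6 largest falls per comparison among called genes whose samples do not overlap between groups, and up to 4 called members per list with any called member opposite to its list. The blocks and sets by background level and median scaling over detected probes were added after the data were seen.

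Limma and camera were tested on simulated data of 11754 genes. For leiomyosarcoma against muscle, 81% of 100 genes changed by 2 log2 and 93% of 100 changed by 4 were recovered, with 9 false calls. The shares were 75% and 98% with 5 false calls for osteosarcoma against bone marrow. For osteosarcoma against leiomyosarcoma they were 89% and 99% with 6 false calls, and for genes that differ in all 4 contrasts 74% and 96% with 0 false calls. No gene was recovered in the wrong direction. Camera called 2 of 2 planted lists and 0 others, which leaves lists of correlated genes open. Figures were drawn with matplotlib (3.10.9, Python 3.11.15).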

Results

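Gene expression was measured in 12 fresh-frozen mouse tissue samples on one-colour Illumina bead arrays of 45281 probes each. The samples were 2 of normal muscle, 2 of normal bone marrow, 4 of leiomyosarcoma, a malignant tumour named for smooth muscle, and 4 of osteosarcoma, a malignant tumour of bone. The labels gave all 12 samples, normal tissue included, the same floxed p53 genotype, and named neither a recombinase nor the sex of the animals. Trp53 itself, like Mki67, was not analysed here because the probe annotation used here lists no probe for it, so the targeted gene could not be checked. Between 14169 and 18100 probes per array (31.3% to 40.0%) were detected, and 11754 genes entered the tests. Replicates correlated across genes, which are not independent, at 0.935 in muscle, 0.983 in bone marrow, 0.946 to 0.974 in leiomyosarcoma and 0.916 to 0.956 in osteosarcoma. The labels do not state that every sample came from a separate animal, and 1 muscle and 1 bone marrow sample share an animal code, so p-values measure only the spread between these samples. The number of arrays limits the precision of every value.

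The arrays fell into 2 sets by background. The background constant lay between 80.8 and 84.2 on 6 arrays (both normal tissues and leiomyosarcomas 1 and 2) and between 99.3 and 110.1 on the other 6 (leiomyosarcomas 3 and 4 and all osteosarcomas). Leiomyosarcomas 3 and 4 differed from leiomyosarcomas 1 and 2 in 0 genes in limma after adjustment, with 605 genes at an unadjusted p under 0.05. Values with the background level as a block, or within one set of arrays, are therefore given beside each comparison below. Values are on the log2 scale of normalised signal. Where a gene was not detected on any array of a group, its difference is given as "at least N-fold", computed on each array against the lowest signal of a detected probe, or the signal of the gene itself where higher. A gene counted as detected on an array where any of its probes was, and where the probe used was detected on fewer arrays this is said. Where a group lies near or under the lowest detected signal, neither the size of a difference nor its rank is exact. Called values that moved by over 1.5-fold without 1 sample are given with it left out. The files mark no saturated probes, and Mmp13 in osteosarcomas 2 and 4 and Pvalb in muscle 2 held the highest signal of their array, so whether such probes were saturated is unknown. List medians "with bounds" have such genes at that bound.

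The first comparison asked how leiomyosarcoma differed from normal muscle. Genes of the skeletal muscle contractile apparatus were far lower in the tumours, while genes of mitosis, DNA replication, macrophages and extracellular matrix were higher, list calls of which 0 held with an estimated correlation. Tnnc2, the troponin C of fast skeletal fibres, fell by 10.59 ± 1.49 (SE), from 15.78 ± 0.09 (SD, n = 2) in muscle to 5.19 ± 1.05 (n = 4; adjusted p = 0.000143), and was detected on 1 of 4 leiomyosarcomas. Crabp1, a cytoplasmic retinoic acid-binding protein, reached 11.63 ± 0.89 (n = 4) against 4.91 ± 0.50 (n = 2) in muscle, where it was not detected, at least 64.8-fold higher (adjusted p = 1.3e-06). In all, 2358 genes rose and 1778 fell.

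After Crabp1, the rises named by fitted difference were in Acpp, the prostatic acid phosphatase (at least 32.1-fold), Lxn, a carboxypeptidase inhibitor (at least 30.7-fold), Ptn, the growth factor pleiotrophin (at least 33.9-fold), Prl2c3, a proliferin (at least 28.0-fold), and Fcrls, an Fc receptor-like gene of myeloid cells (5.36 ± 0.82). These bounds do not order the genes. The other probe of Acpp gave 1.52. Prl2c3 has near-identical copies, so which copy was measured is uncertain, and with the background block its fitted difference was 4.02 in place of 5.36, less than its bound, while without leiomyosarcoma 2 the bound was 48.9-fold. After Tnnc2, the falls named by fitted difference were in Pvalb, the calcium buffer parvalbumin (−10.45 ± 1.59), Ckm, muscle creatine kinase (−10.33 ± 1.22), Tnnt3, fast troponin T (−9.93 ± 1.19), Tcap, the titin cap (−9.89 ± 1.48), and Actn3, the alpha-actinin of fast fibres (−9.81 ± 1.09). Pvalb, Ckm, Tnnt3 and Actn3 were each detected on 1 of 4 leiomyosarcomas and Tcap on 3, the probe used on 2, so these sizes and their order are not exact. The adjusted p-values of these 10 genes lay between 6.5e-07 and 0.000272.

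All 19 measured genes of the skeletal muscle fibre list fell, 19 adjusted over the list alone. Their median was −9.11, −9.81 without leiomyosarcoma 2, or −9.02 with bounds (adjusted p = 3.4e-11, and adjusted p = 0.242 with an estimated correlation). In the list of myogenic regulators and embryonic muscle genes 9 of 10 fell, 9 adjusted over the list alone. Mean signal over it was 9.34 and 11.57 in the 2 muscles, and without muscle 1 or 2 the median was −5.07 or −2.90. With both muscles their median was −3.52, or −3.35 with bounds (adjusted p = 1.6e-05, and adjusted p = 0.242 with an estimated correlation). Myf6, a muscle-specific transcription factor, changed by −7.82 ± 0.88 (−8.54 and −7.10 without muscle 1 or 2) and was detected on 1 of 4 tumours. Des, the muscle intermediate filament desmin, changed by −7.21 ± 1.52, and Chrng, the embryonic acetylcholine receptor subunit, was at least 44.0-fold lower, from levels of 8.33 and 13.02 in the 2 muscles, and at least 223-fold or 8.67-fold lower without muscle 1 or 2. Of 13 smooth muscle genes, 3 fell, 2 rose and 8 were not called (5 called adjusted over the list alone; median −0.38, or −0.09 with bounds; adjusted p = 0.316). Those that fell were Hspb6, a small heat shock protein (−4.85 ± 0.89, −5.44 without leiomyosarcoma 2), Synpo2, an actin-binding protein (at least 8.56-fold lower), and Myh11, the smooth muscle myosin heavy chain (at least 5.85-fold lower). Pdlim7, an actin-associated scaffold (2.41 ± 0.29), and Cald1, caldesmon (2.01 ± 0.41), rose. The probe used for Cald1 was detected in neither muscle, which makes it at least 1.90-fold higher, and another of its probes on 1 of 2.

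Proliferation genes were higher in leiomyosarcoma. In the mitosis list 11 of 14 rose, 11 adjusted over the list alone. Their median was 2.33, or 2.34 with bounds (adjusted p = 5.5e-06, and 0.242 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, rose by 4.85 ± 0.33, having been detected on 1 of 2 muscles. Cdk1, the mitotic kinase, was at least 16.7-fold higher, and Plk1, polo-like kinase, at least 12.5-fold higher. In the DNA replication list 15 of 16 rose, 15 adjusted over the list alone. Their median was 2.45, or 2.22 with bounds (adjusted p = 1.0e-07, and 0.205 with an estimated correlation). E2f1, the S-phase transcription factor, was at least 13.0-fold higher, and the helicase subunits Mcm5 and Mcm6 rose by 3.92 ± 0.31 and 3.14 ± 0.34. Tyms, thymidylate synthase, rose by 4.34 ± 0.50 on the probe used, detected on 1 of 2 muscles, while its other probes gave −0.30 to 1.47. Without muscle 1 or 2 it was 5.18 or 3.49.

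Matrix and macrophage genes were higher as well. Of 16 collagen and stromal matrix genes, 14 rose, 15 adjusted over the list alone, among them Fn1, fibronectin (4.59 ± 0.83), Tnc, tenascin C (4.65 ± 0.93, adjusted p = 0.00159, and 0.0698 within the low-background arrays), and Col5a1 (3.45 ± 0.48). Without muscle 1 or 2 Fn1 was 5.78 or 3.41 and Col5a1 4.39 or 2.52, and Tnc was 4.03 or 5.45 without leiomyosarcoma 1 or 2. The median of the list was 2.95 (3.57 or 2.03 without muscle 1 or 2), also 2.95 with bounds (adjusted p = 0.000101, and adjusted p = 0.299 with an estimated correlation). Of 13 matrix proteases and inhibitors, 12 rose, 12 adjusted over the list alone. Their median was 2.85, also with bounds (adjusted p = 5.5e-06, and 0.0693 with an estimated correlation). Mmp14, a membrane-bound metalloprotease, rose by 4.15 ± 0.49 and Mmp3, stromelysin 1, by 3.91 ± 0.74 (4.57 or 3.25 without muscle 1 or 2). Mmp13, a collagenase, rose by 4.82 ± 0.38 on the probe used, detected on 1 of 2 muscles, while its other probes gave −0.64 to 0.12. Among 12 macrophage genes 10 rose and 1 fell, 12 called adjusted over the list alone. Their median was 3.49 (2.65 without muscle 2), also 3.49 with bounds (adjusted p = 0.000236, and adjusted p = 0.299 with an estimated correlation). The complement genes C1qa (4.06 ± 0.49, detected on 1 of 2 muscles) and C1qb (3.80 ± 0.64) rose, as did the myeloid receptor Trem2 (3.66 ± 0.48, detected on 1 of 2 muscles). Without muscle 1 or 2 C1qa was 4.72 or 3.40, C1qb 4.84 or 2.76 and Trem2 4.61 or 2.72. Cd163, a haemoglobin scavenger receptor, changed by −1.81 ± 0.52 (adjusted p = 0.0135), a call that ended without muscle 1 (−0.96, adjusted p = 0.208; −2.67 without muscle 2) and with the background block (−1.29, adjusted p = 0.0831).

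Oxidative phosphorylation genes were lower in leiomyosarcoma. Of 15 oxidative phosphorylation genes, 14 fell, 14 adjusted over the list alone. Their median was −2.13, also with bounds (adjusted p = 7.2e-08, and 0.205 with an estimated correlation). The heart and muscle isoforms of cytochrome oxidase led, with Cox8b at least 384-fold lower, Cox6a2 at −9.18 ± 1.36 (detected on 1 of 4 tumours) and Cox7a1 at −6.47 ± 0.74 (−5.35 or −7.59 without muscle 1 or 2), whereas Cycs, cytochrome c, changed by −2.50 ± 0.28. Glycolysis genes moved both ways, 4 up and 3 down of 11 (7 called adjusted over the list alone, adjusted p = 0.911), with the glucose transporter Slc2a1 at 3.01 ± 0.39 and the aldolase of muscle, Aldoa, at −3.96 ± 0.35. Adipocyte genes fell in 4 of 6 cases, 4 adjusted over the list alone, including Lpl, lipoprotein lipase (−4.32 ± 0.67). Their median was −1.39, or −1.07 with bounds (adjusted p = 0.00772, and adjusted p = 0.205 with an estimated correlation). Ribosomal protein genes rose in 7 of 11 cases, 7 adjusted over the list alone, with Rpl3 at 2.05 ± 0.20. Their median was 1.07, also with bounds (adjusted p = 0.00033, and adjusted p = 0.205 with an estimated correlation). In the list of receptor tyrosine kinases and ligands 7 of 14 rose, 7 adjusted over the list alone. Their median was 1.25, or 1.07 with bounds (adjusted p = 0.0134, and adjusted p = 0.205 with an estimated correlation). Kit, the stem cell factor receptor, was at least 6.42-fold higher, Hgf, hepatocyte growth factor, at least 4.35-fold higher, and the receptor Axl rose by 2.95 ± 0.41 (3.58 or 2.33 without muscle 1 or 2). Without muscle 2 this list was not called (adjusted p = 0.0634).

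Among p53 target genes, 6 of 17 fell and 0 rose, 6 called adjusted over the list alone. Their median was −0.63, also with bounds (adjusted p = 0.0262, and adjusted p = 0.205 with an estimated correlation). Ccng1, cyclin G1, changed by −4.28 ± 0.30, from 12.19 ± 0.27 (n = 2) in muscle to 7.92 ± 0.39 (n = 4; adjusted p = 1.4e-06), Phlda3, an inhibitor of Akt signalling, by −2.97 ± 0.29 and Ddit4l by −4.12 ± 0.83 (−3.47 or −4.77 without muscle 1 or 2). Mdm2, the ubiquitin ligase of p53, changed by −1.25 ± 0.26 (adjusted p = 0.00229). Cdkn1a, the cell cycle inhibitor p21, stood at 9.18 and 13.58 in the 2 muscles and did not pass the test (−2.37 ± 0.94, adjusted p = 0.0565; −4.57, which was called, and −0.18 without muscle 1 or 2). The list call depended on muscle 2, without which it ended (adjusted p = 0.0917), and it also ended with median scaling over detected probes (adjusted p = 0.0572). Without muscle 2 Mdm2 changed by −0.77, under the fold minimum, and within the low-background arrays its adjusted p was 0.0742. Cdkn2a, which encodes p16 and p19Arf, was at least 8.17-fold higher on the probe used, which was not detected in muscle (4.66 ± 0.09, n = 2, against 8.64 ± 0.76, n = 4; adjusted p = 1.6e-05). Its other probes, of which at least 1 was detected on each muscle, differed by 1.53 to 2.51 and were not tested. Rb1, the retinoblastoma protein, changed by −1.95 ± 0.44 (adjusted p = 0.00331), a call that ended without muscle 2 (−1.05, adjusted p = 0.0572; −2.85 without muscle 1) and within the low-background arrays (adjusted p = 0.0943). Top2a, the topoisomerase of dividing cells, was at least 7.94-fold higher. Myc, not detected in muscle, was at least 1.20-fold higher and not called, its difference of 0.76 ± 0.26 lying under the fold minimum (adjusted p = 0.0294).

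**Figure D1:**
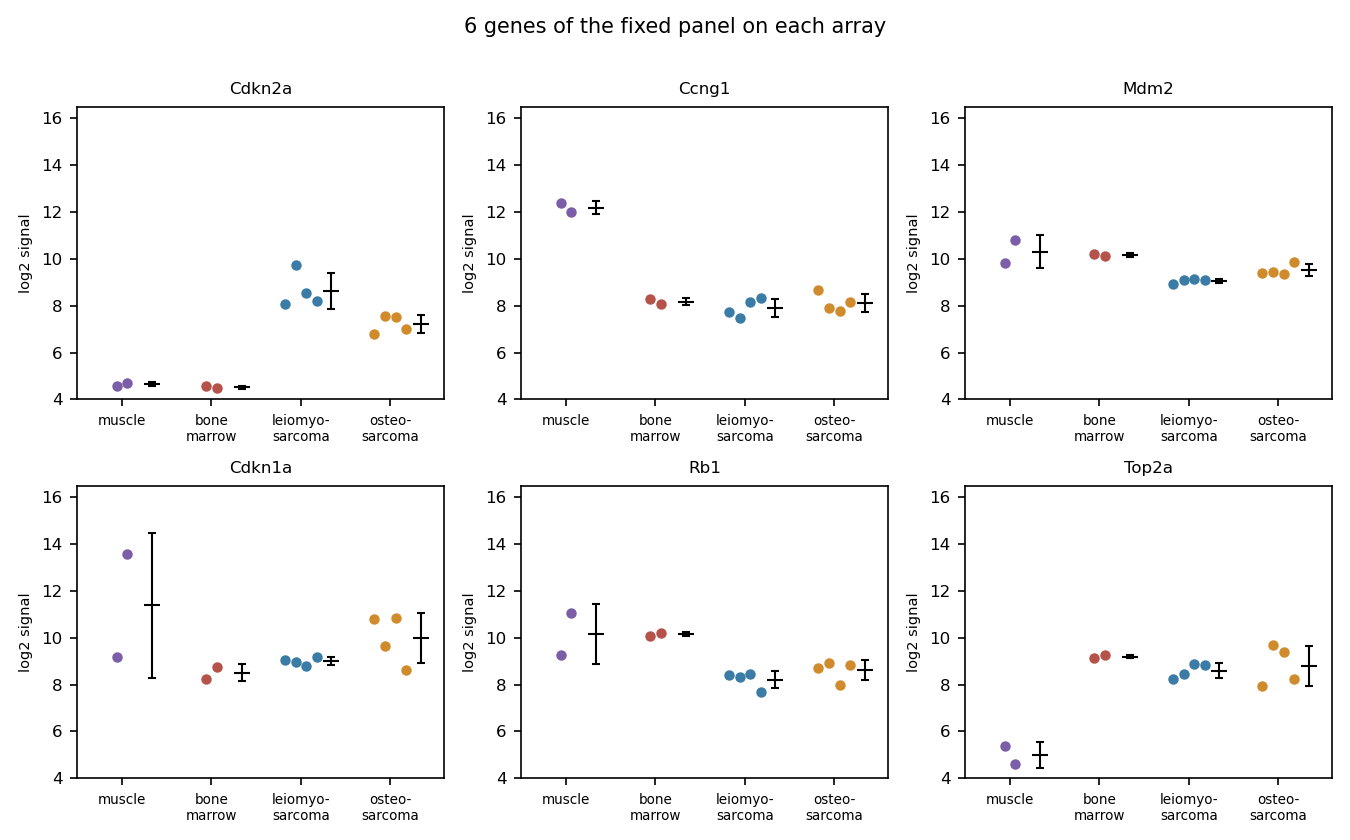
Log2 normalised signal of Cdkn2a, Ccng1, Mdm2, Cdkn1a, Rb1 and Top2a (vertical axis) in muscle (n = 2), bone marrow (n = 2), leiomyosarcoma (n = 4) and osteosarcoma (n = 4), 1 point per array, with the dash and bar giving the group mean ± SD. Cdkn2a lies at 4.66 ± 0.09 in muscle and 8.64 ± 0.76 in leiomyosarcoma, and the 2 muscles lie apart at 9.18 and 13.58 for Cdkn1a.

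Of the other lists, B lymphoid and erythroid genes were not called in any member (0 adjusted over the list alone, adjusted p = 0.883 and 0.848). The neutrophil list had 1 gene up and 3 down of 15 (2 called adjusted over the list alone, adjusted p = 0.316). Interferon response genes rose in 3 of 9 cases (2 adjusted over the list alone, adjusted p = 0.191) and Wnt genes in 3 of 9 (1 adjusted over the list alone, adjusted p = 0.62). Oncofetal genes rose in 3 and fell in 1 of 8 cases (4 called adjusted over the list alone, adjusted p = 0.705), with Dlk1 at 4.97 ± 0.84 (4.30, 5.64 and 5.68 without muscle 1, muscle 2 or leiomyosarcoma 2). Handling genes rose in 2 of 12 cases (2 adjusted over the list alone, adjusted p = 0.539), a list that was called without muscle 2 (adjusted p = 0.0415). Osteoblast, chondrocyte, osteoclast, T and NK lymphoid, endothelial, hypoxia and sex-linked genes were not called as lists (adjusted p = 0.947, 0.789, 0.848, 0.599, 0.883, 0.599 and 0.883).

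In this comparison 12 of 28 lists were called and 0 of them with an estimated correlation. All 12 were also called with the background block and within the low-background arrays. The block gave 2214 higher and 1643 lower genes, of which 3597 were among the 4136 called without it, and the low-background arrays gave the same counts with the spread of all 12 arrays. Of 95 called named genes 6 moved by over 1.5-fold with the block, among them Hspb6 (−3.91), Des (−6.30) and Lpl (−3.44). Fitted to the 6 low-background arrays alone, which estimates the spread from fewer samples, the counts were 1772 and 1271.

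The second comparison asked how osteosarcoma differed from normal bone marrow. Genes of neutrophils and their precursors, and of red cell and lymphocyte lineages, were lower in the tumours, and genes of bone matrix, osteoblasts, collagens, matrix proteases, endothelium and macrophages were higher. Of these list calls only those of neutrophil and of matrix protease genes held with an estimated correlation. Lcn2, the neutrophil granule protein lipocalin 2, fell by 10.71 ± 0.41 (SE), from 15.75 in both marrows to 5.04 ± 0.38 (SD, n = 4), and was detected on 2 of 4 osteosarcomas (adjusted p = 5.5e-09). Col1a1, the main chain of bone collagen, reached 14.49 ± 0.44 (n = 4) and was not detected in bone marrow (4.62 ± 0.004, n = 2), at least 519-fold higher (adjusted p = 8.1e-08). In all, 1745 genes rose and 1528 fell.

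Sparc, the bone matrix protein osteonectin, rose by 9.63 ± 0.47 (adjusted p = 3.3e-08), Serpinh1, the collagen chaperone, by 8.92 ± 0.41, Mmp13 by 8.92 ± 0.38, Ctsk, the collagen-degrading protease cathepsin K, by 8.29 ± 0.92 (8.89 without osteosarcoma 2) and Scarf2 by 8.17 ± 0.37. Ctsk and Scarf2 were detected on 1 of 2 marrows, and the other probes of Mmp13 gave 2.62 to 5.71. Ltf, lactotransferrin, changed by −10.32 ± 0.34 (detected on 1 of 4 tumours) and Camp, the cathelicidin, by −9.74 ± 0.30 (detected on 1 of 4). Ngp, a neutrophil granule protein, was at least 868-fold lower, Retnlg, a resistin-like protein of neutrophils, at least 669.8-fold lower, and Prg2, the eosinophil major basic protein, at least 873-fold lower.

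All 15 genes of the neutrophil and myeloid precursor list fell (15 adjusted over the list alone; median −8.79, also −8.79 with bounds; adjusted p = 1.8e-20). This call held with an estimated correlation (adjusted p = 0.00697). Mean signal over that list was 13.76 and 13.90 in the marrows and between 5.18 and 5.92 on all other arrays. Erythroid genes fell in 7 of 8 cases, 7 adjusted over the list alone, including the anion exchanger Slc4a1 (−6.81 ± 0.74, detected on 1 of 4 tumours) and Car1, carbonic anhydrase 1 (at least 10.98-fold lower). Their median was −3.38, also with bounds (adjusted p = 0.000445, and 0.137 with an estimated correlation). B lymphoid genes fell in 5 of 8 cases, 5 adjusted over the list alone, with the surrogate light chain genes Vpreb3 at least 17.4-fold and Igll1 at least 9.84-fold lower. Without bone marrow 1 or 2 these bounds were 9.43 or 31.95 for Vpreb3 and 5.27 or 18.4 for Igll1, and the list median was −1.05 or −2.90. Their median was −1.91 with both, or −1.58 with bounds (adjusted p = 0.00212, and adjusted p = 0.326 with an estimated correlation). T and NK lymphoid genes fell in 5 of 8 cases, 5 adjusted over the list alone, among them the granule protein Nkg7 (−6.75 ± 0.47, detected on 3 of 4 tumours) and Cd3d, a T cell receptor subunit (−6.32 ± 0.42, detected on 2 of 4). Their median was −1.30, or −1.12 with bounds (adjusted p = 0.00126, and adjusted p = 0.22 with an estimated correlation).

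Bone genes rose in osteosarcoma. Of 13 osteoblast and bone matrix genes, 9 rose and 0 fell, 9 adjusted over the list alone. Their median was 4.82, or 4.37 with bounds (adjusted p = 6.9e-06, and 0.0593 with an estimated correlation). Sp7, the osteoblast transcription factor osterix, reached 12.29 ± 0.24 (n = 4) against 4.58 ± 0.03 (n = 2) and was at least 113-fold higher on the probe used (adjusted p = 2.9e-10). The osteocalcin genes Bglap2 and Bglap, near-identical copies whose probes are uncertain, were at least 206-fold and at least 72.4-fold higher, and Ibsp, bone sialoprotein, rose by 7.63 ± 1.24 (detected on 1 of 2 marrows). Without osteosarcoma 2 the bound of Bglap2 was 126-fold and that of Bglap 40.5-fold, without osteosarcoma 3 329-fold and 119.8-fold, and without osteosarcoma 4 that of Bglap was 111-fold. Ibsp was 6.89, 8.37, 8.93 and 7.02 without bone marrow 1, bone marrow 2, osteosarcoma 2 or osteosarcoma 4. Chondrocyte genes rose in 3 of 5 cases, 3 adjusted over the list alone, with the cartilage regulator Sox9 at least 35.8-fold and the collagen Col2a1 at least 8.12-fold higher. Their median was 3.51, or 3.26 with bounds (adjusted p = 0.0265, and 0.137 with an estimated correlation). Osteoclast genes rose in 5 of 7 cases, 5 adjusted over the list alone, with Tnfrsf11a, the receptor RANK, at least 5.02-fold higher and Acp5, the tartrate-resistant phosphatase, at least 8.58-fold higher (adjusted p = 0.00273, and 0.0782 with the background block; at least 12.96-fold without osteosarcoma 2). Their median was 2.98, or 2.44 with bounds (adjusted p = 0.0265, and 0.521 with an estimated correlation). Mean signal over the osteoclast list was 9.60 and 9.86 in osteosarcomas 1 and 4 but 7.04 and 7.51 in osteosarcomas 2 and 3, against 5.391 and 5.596 in bone marrow. The chondrocyte and osteoclast calls ended with median scaling (adjusted p = 0.106 and 0.0877).

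Matrix, vessel and macrophage genes rose too. Of 16 collagen and matrix genes, 13 rose, 13 adjusted over the list alone, including Tnc (7.60 ± 0.93) and Col6a1 (6.86 ± 0.87, its probe detected on 1 of 2 marrows; 7.52 or 6.14 without osteosarcoma 2 or 4). Their median was 5.94, or 5.35 with bounds (adjusted p = 1.3e-08, and 0.137 with an estimated correlation). Matrix proteases and inhibitors rose in 9 and fell in 1 of 13 cases (11 called adjusted over the list alone; median 3.57, or 2.79 with bounds; adjusted p = 6.9e-06, kept at adjusted p = 0.0337 with an estimated correlation). Timp1, an inhibitor of metalloproteases, rose by 7.76 ± 0.47 (detected on 1 of 2 marrows), and the member that fell was Plaur, the urokinase receptor (−1.76 ± 0.22). Endothelial genes rose in 10 of 12 cases, 11 adjusted over the list alone, with the sialomucin Emcn at least 17.4-fold and the cadherin Cdh5 at least 5.77-fold higher. Their median was 2.42, or 1.98 with bounds (adjusted p = 0.000834, and 0.396 with an estimated correlation). Macrophage genes rose in 8 of 12 cases, 9 adjusted over the list alone, with C1qa at least 9.87-fold higher and C1qc at 4.04 ± 0.64. Their median was 1.75, also with bounds (adjusted p = 0.000455, and adjusted p = 0.326 with an estimated correlation). Wnt pathway targets and antagonists rose in 5 of 9 cases, 5 adjusted over the list alone, led by the matricellular protein Ccn4 (6.54 ± 0.25, detected on 1 of 2 marrows) and the antagonist Dkk3 (at least 29.6-fold). Their median was 2.00, or 1.12 with bounds (adjusted p = 0.00372, and 0.0751 with an estimated correlation). Receptor tyrosine kinases and ligands rose in 10 and fell in 3 of 14 cases, 13 called adjusted over the list alone. Their median was 2.27, or 2.05 with bounds (adjusted p = 0.00441, and adjusted p = 0.137 with an estimated correlation). Pdgfa, a platelet-derived growth factor, was at least 54.2-fold higher and its receptor gene Pdgfra at least 45.3-fold higher (at least 26.2-fold without osteosarcoma 2), while Kit (−2.69 ± 0.36) and Hgf (−2.55 ± 0.31, detected on 1 of 4 tumours) fell. This list was not called on the authors' unsubtracted signals (adjusted p = 0.189).

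Proliferation genes were lower in osteosarcoma than in bone marrow. DNA replication genes fell in 8 of 16 cases, 9 adjusted over the list alone, with Mcm5 at −2.002 ± 0.31 and the flap endonuclease Fen1 at −1.80 ± 0.27. Their median was −1.02, also with bounds (adjusted p = 0.000485, and adjusted p = 0.326 with an estimated correlation). In the mitosis list 3 of 14 fell, 3 adjusted over the list alone, led by the kinesin Kif11 (−1.58 ± 0.33), and without bone marrow 2 the list was not called (adjusted p = 0.0605). Their median was −0.66, also with bounds (adjusted p = 0.0124, and adjusted p = 0.486 with an estimated correlation). The interferon response list was called higher with 3 of 9 genes up, 3 adjusted over the list alone. Their median was 1.62, also with bounds (adjusted p = 0.0468, and adjusted p = 0.538 with an estimated correlation). That call ended with the background block (adjusted p = 0.262), with median scaling (0.112), and without bone marrow 2 (0.0939), leiomyosarcoma 1 (0.0503) or 2 (0.0558), or osteosarcoma 3 (0.0931) or 4 (0.086). Oxidative phosphorylation genes were called higher with 2 of 15 up, 2 adjusted over the list alone. Their median was 0.68, also with bounds (adjusted p = 0.0389, and adjusted p = 0.538 with an estimated correlation). This call ended with the background block (adjusted p = 0.174), with median scaling (0.106), and without bone marrow 1 (0.0584) or 2 (0.0548) or osteosarcoma 1 (0.06) or 4 (0.086). Mean signal over this list, which holds the muscle isoforms Cox8b, Cox6a2 and Cox7a1, was 10.96, 9.87, 10.004 and 10.69 in osteosarcomas 1 to 4, the same order as for skeletal muscle fibre genes.

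Skeletal muscle signal differed among the osteosarcomas, and osteosarcoma 2 lay near bone marrow. Mean signal over the skeletal muscle fibre list was 11.03, 5.28, 7.21 and 7.92 in osteosarcomas 1 to 4, against 5.15 and 5.01 in bone marrow and 14.21 and 14.02 in muscle. The list was called higher than in bone marrow with 3 of 19 genes up, 0 adjusted over the list alone, and the call ended with median scaling (adjusted p = 0.106). Their median was 2.78 (1.78 or 3.76 without osteosarcoma 1 or 2), or 2.69 with bounds (adjusted p = 0.0076, and adjusted p = 0.538 with an estimated correlation). Eno3, the enolase of muscle, rose by 2.65 ± 0.73 (adjusted p = 0.0143), not called without bone marrow 1 (adjusted p = 0.0817) or 2 (0.0859). The myogenic list was not called (2 of 10 up, 2 adjusted over the list alone, adjusted p = 0.0554) but passed without muscle 1 or 2 (adjusted p = 0.0431 each), osteosarcoma 2 (0.0224) or osteosarcoma 3 (0.0445). Within it Cdh15, the cadherin of muscle precursor cells, was at least 10.8-fold higher in osteosarcoma. Smooth muscle genes rose in 3 of 13 cases (3 adjusted over the list alone, adjusted p = 0.0859).

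Among the panel genes Cdkn2a was at least 3.36-fold higher on the probe used, which was not detected in bone marrow (4.51 ± 0.05, n = 2, against 7.22 ± 0.38, n = 4; adjusted p = 0.000282). Its other probes differed by 0.61 to 0.88. Rb1 changed by −1.52 ± 0.44 (adjusted p = 0.0171), a call that ended with the background block (adjusted p = 0.262) and without bone marrow 1 (0.0799) or 2 (0.109). Cdkn1a (1.47 ± 0.94, adjusted p = 0.244), Mdm2 (−0.65 ± 0.26, adjusted p = 0.0729), Ccng1 (−0.05 ± 0.30, adjusted p = 0.912), Myc (0.04 ± 0.26, adjusted p = 0.92, detected on 3 of 4 osteosarcomas) and Top2a (−0.39 ± 0.45, adjusted p = 0.531) did not pass. Of 17 p53 target genes 3 rose and 3 fell (6 called adjusted over the list alone, adjusted p = 0.867), with Phlda3 at least 8.51-fold higher and the p53-inducible nuclear protein Trp53inp1 at −2.05 ± 0.33. The lists not called were hypoxia (4 of 10 up, 4 adjusted over the list alone, adjusted p = 0.0519), oncofetal and imprinted genes (3 of 8 up, 3 adjusted over the list alone, adjusted p = 0.0859), handling and stress genes (1 of 12 up and 4 down, 5 called adjusted over the list alone, adjusted p = 0.501), ribosomal protein genes (0 of 11, 0 adjusted over the list alone, adjusted p = 0.253), glycolysis (0 of 11, 0 adjusted over the list alone, adjusted p = 0.877), adipocyte genes (0 of 6, 0 adjusted over the list alone, adjusted p = 0.787) and sex-linked genes (1 of 4 up, 1 adjusted over the list alone, adjusted p = 0.844). The hypoxia list passed without leiomyosarcoma 3 (adjusted p = 0.0488) or 4 (0.0468) or osteosarcoma 2 (0.0343) or 4 (0.0379). P4ha2, a collagen prolyl hydroxylase of the hypoxia list, was at least 67.5-fold higher, and the imprinted gene Mest at least 11.4-fold.

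No background level held both osteosarcoma and bone marrow, so the block rests on the leiomyosarcomas that span both levels. With it 1105 genes were higher and 1110 lower, of which 2010 were among the 3273 called without it and 0 had the opposite direction. Of 98 called named genes 25 moved by over 1.5-fold with the block, among them Sparc (10.33), Mmp13 (9.56), Timp1 (8.49), Col2a1 (5.08), Mest (6.16), Eno3 (3.67), Slc4a1 (−8.48), Hgf (−1.84) and Tnfrsf11a (2.22, less than its bound). Of 28 lists 18 were called, 17 with the block, which also called the oncofetal list (adjusted p = 0.0169), and 2 with an estimated correlation.

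**Figure D2:**
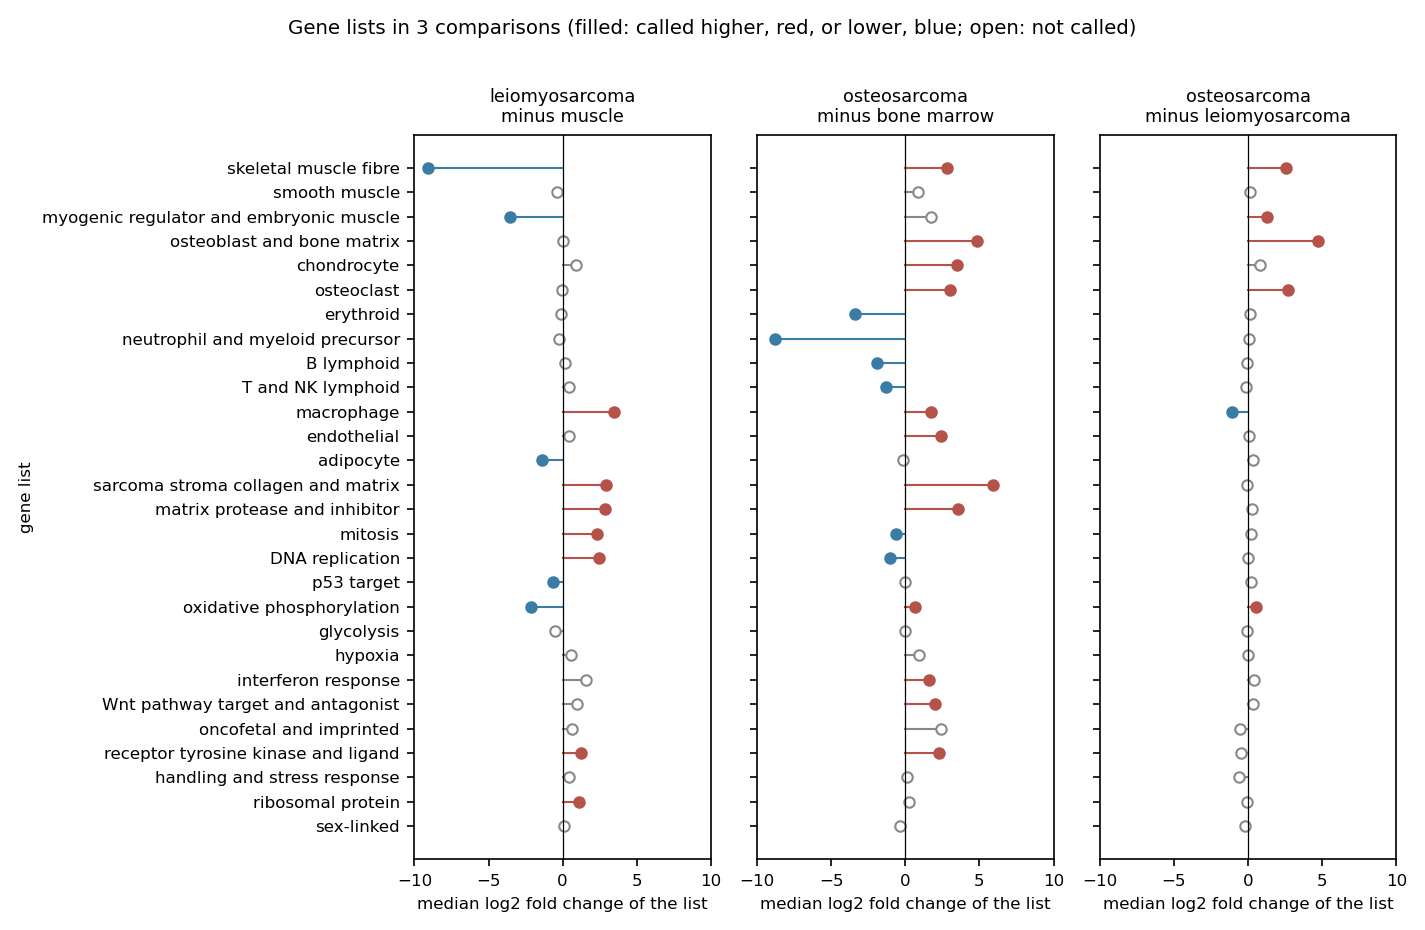
Median log2 fold change (horizontal axis) of the genes of each of the 28 lists (vertical axis) in leiomyosarcoma against muscle, osteosarcoma against bone marrow and osteosarcoma against leiomyosarcoma, with filled red points for lists called higher, filled blue points for lists called lower and open points for lists not called. The skeletal muscle fibre list lies at −9.11 in leiomyosarcoma against muscle and the neutrophil list at −8.79 in osteosarcoma against bone marrow, while mitosis genes lie at 2.33 in the first comparison and −0.66 in the second.

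The third comparison asked how the tumour types differed from each other. Osteosarcomas carried high levels of bone-forming genes, whose mean signal in leiomyosarcomas lay near that of the normal tissues. Sp7 was at 12.29 ± 0.24 (n = 4) in osteosarcoma and not detected in any leiomyosarcoma, at least 135-fold higher on the probe used (adjusted p = 1.8e-10), while its other probe gave 3.76 log2. Ibsp stood at 13.47 ± 2.62 (n = 4) in osteosarcoma against 5.12 ± 0.27 (n = 4), a fold difference of 326 (adjusted p = 0.000466), and was detected on 2 of 4 leiomyosarcomas. Ibsp was at 9.58 in osteosarcoma 2, without which the difference was 9.64 log2 in place of 8.35, and it was 7.74 without osteosarcoma 4. Leiomyosarcomas were marked by Crabp1, which was not detected in osteosarcoma (4.98 ± 0.15, n = 4, against 11.63 ± 0.89, n = 4) and was at least 84.4-fold lower there (adjusted p = 1.1e-06). In all, 389 genes were higher in osteosarcoma and 510 lower.

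Besides Sp7 and Ibsp, the genes highest in osteosarcoma were Bglap2 (8.01 ± 0.80, detected on 1 of 4 leiomyosarcomas), Bglap (at least 86.8-fold), Panx3, a pannexin channel of bone and cartilage cells (6.84 ± 0.49, adjusted p = 6.2e-06, detected on 3 of 4 leiomyosarcomas), and Xist, the noncoding RNA of the inactive X chromosome (at least 47.4-fold; adjusted p = 0.00136). Besides Crabp1, those lowest in osteosarcoma were Dlk1, an imprinted Notch ligand family member (−6.12 ± 0.68), Mmp3 (−5.71 ± 0.61), Acpp (−5.55 ± 0.42), Prl2c3 (−5.36 ± 0.66) and Twist2, a mesenchymal transcription factor (at least 26.6-fold lower, adjusted p = 7.1e-08). Dlk1 and Mmp3 were detected on 3 of 4 osteosarcomas, and Acpp and Prl2c3 on 1. The other probe of Acpp gave −1.42 and that of Bglap 1.16. Without osteosarcoma 2 or 3 Bglap2 was 7.297 or 8.68, and without osteosarcoma 2, 3 or 4 Bglap was at least 48.6-fold, 143.5-fold or 133-fold higher. Without leiomyosarcoma 2 Dlk1 was −6.84 and Prl2c3 −6.17.

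**Figure D3:**
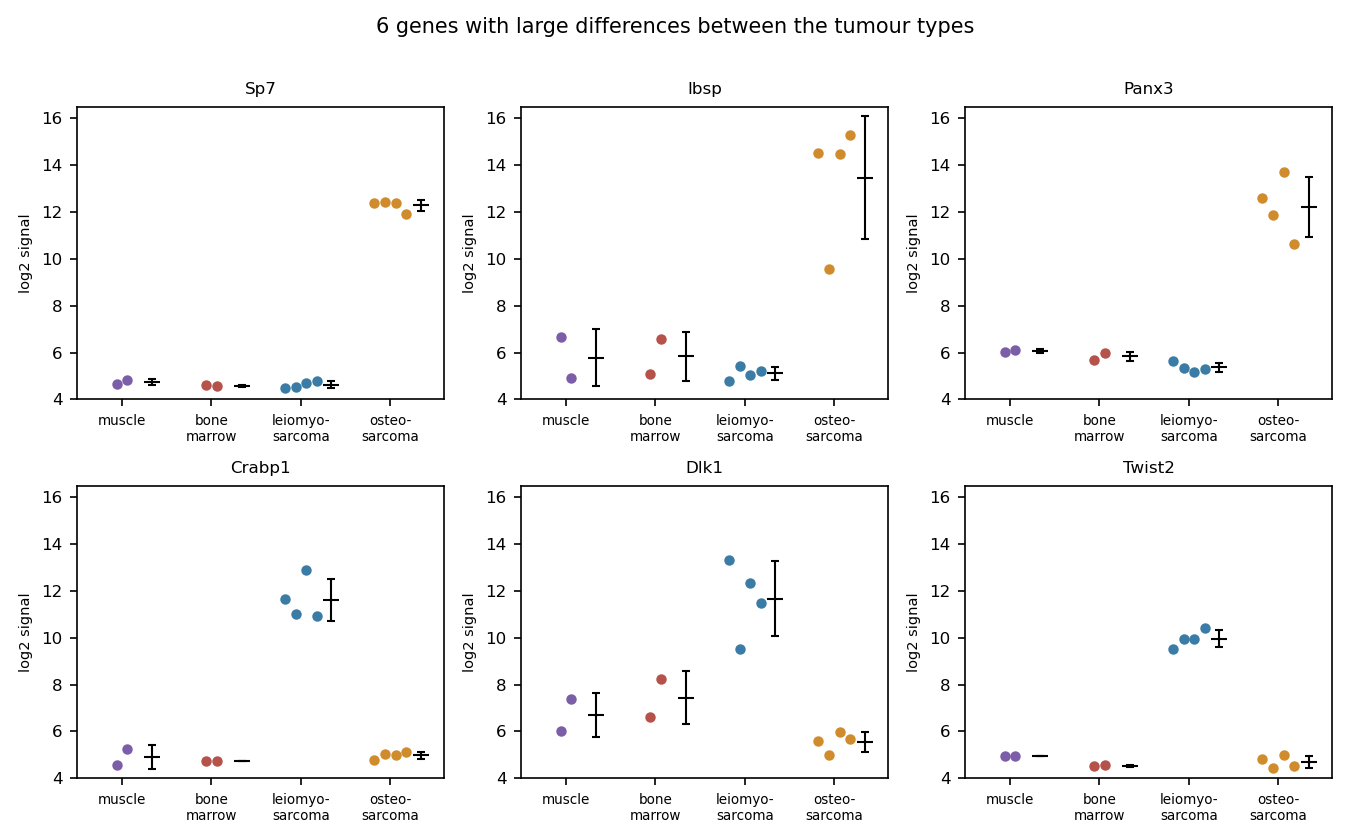
Log2 normalised signal of Sp7, Ibsp, Panx3, Crabp1, Dlk1 and Twist2 (vertical axis) in muscle (n = 2), bone marrow (n = 2), leiomyosarcoma (n = 4) and osteosarcoma (n = 4), 1 point per array, with the dash and bar giving the group mean ± SD. Sp7 lies at 12.29 ± 0.24 in osteosarcoma and near background elsewhere, and Crabp1 at 11.63 ± 0.89 in leiomyosarcoma and 4.98 ± 0.15 in osteosarcoma.

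Of 13 osteoblast and bone matrix genes 9 rose and 0 fell (9 adjusted over the list alone; median 4.72, also 4.72 with bounds; adjusted p = 3.1e-12), a call kept with an estimated correlation (adjusted p = 0.0149) and within the high-background arrays (adjusted p = 3.0e-08). Mean signal over this list was 9.72, 9.31, 8.94 and 8.81 in osteosarcomas 1 to 4 and 4.98 to 5.29 on all other arrays. Osteoclast genes were higher in 4 of 7 cases, 4 adjusted over the list alone, with Acp5 at least 10.3-fold higher (adjusted p = 0.0036, and 0.101 within the high-background arrays; at least 15.5-fold without osteosarcoma 2). As above, osteosarcomas 1 and 4 stood apart, and mean signal over the list was 6.38 to 6.66 in leiomyosarcomas. Their median was 2.68 (3.41 or 1.99 without osteosarcoma 2 or 4), also 2.68 with bounds (adjusted p = 0.00156, and adjusted p = 0.743 with an estimated correlation, and 0.0283 within the high-background arrays). Col1a1 (3.11 ± 0.44) and Col1a2 (2.56 ± 0.36), the chains of type I collagen, and Col5a2 (2.01 ± 0.40) were higher in osteosarcoma. Other probes of Col5a2 gave 0.15 to 0.98. The proteoglycan Vcan (−1.99 ± 0.36, detected on 3 of 4 osteosarcomas) was lower, though not called within the high-background arrays (adjusted p = 0.0817). The collagen and matrix list as a whole was not called, with 4 up and 1 down of 16 (6 called adjusted over the list alone, adjusted p = 0.428). Matrix proteases moved both ways, 4 up and 2 down of 13 (6 called adjusted over the list alone, adjusted p = 0.428), with Mmp13 at 4.87 ± 0.31 and the urokinase Plau at −1.33 ± 0.22. Receptor tyrosine kinases and ligands split 3 up and 3 down of 14 (6 called adjusted over the list alone, adjusted p = 0.468), with the fibroblast growth factor receptor Fgfr2 at 3.67 ± 0.37, Hgf at −2.65 ± 0.25 (detected on 1 of 4 osteosarcomas) and Axl at −1.64 ± 0.33. Glycolysis genes were lower in 2 of 11 cases (2 adjusted over the list alone, adjusted p = 0.428), the larger being Slc2a1 (−2.32 ± 0.32), and the list was called with the background block (adjusted p = 0.0472) and within the high-background arrays (0.0283).

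Macrophage genes were lower in osteosarcoma than in leiomyosarcoma as a list (1 of 12 down and 0 up, 6 adjusted over the list alone). Their median was −1.07, also with bounds (adjusted p = 0.00156, and adjusted p = 0.743 with an estimated correlation, and 0.0072 within the high-background arrays). The member called was Mrc1, the mannose receptor (−2.44 ± 0.52, adjusted p = 0.0114, and 0.115 within the high-background arrays). Skeletal muscle fibre genes were higher as a list (1 of 19 up, 9 adjusted over the list alone), the mean signal over the list being 11.03, 5.28, 7.21 and 7.92 in osteosarcomas against 4.999, 6.54, 5.41 and 4.98 in leiomyosarcomas. Their median was 2.57 (1.37 or 3.52 without osteosarcoma 1 or 2), or 2.63 with bounds (adjusted p = 5.3e-05, and adjusted p = 0.743 with an estimated correlation, and 0.00124 within the high-background arrays). The myogenic list was higher with 2 of 10 up, 2 adjusted over the list alone, but not called without osteosarcoma 1 (adjusted p = 0.161), which had the highest skeletal muscle signal. Their median was 1.30 (0.461 without osteosarcoma 1), or 1.21 with bounds (adjusted p = 0.0168, and adjusted p = 0.743 with an estimated correlation, and 0.0283 within the high-background arrays). Cdh15 was at least 13.0-fold higher in osteosarcoma (adjusted p = 1.9e-06) and kept its call without that sample. Oxidative phosphorylation genes were higher as a list with 0 of 15 called, 0 adjusted over the list alone. Their mean signals ordered the osteosarcomas as the skeletal muscle fibre genes did. Their median was 0.52, also with bounds (adjusted p = 0.00156, and adjusted p = 0.743 with an estimated correlation, and 0.0262 within the high-background arrays). Mitosis (0 of 14, 0 adjusted over the list alone, adjusted p = 0.418) and DNA replication genes (0 of 16, 0 adjusted over the list alone, adjusted p = 0.909) were not called, and mitosis was called higher without osteosarcoma 1 (adjusted p = 0.0483). The interferon list was not called either (0 of 9, 0 adjusted over the list alone, adjusted p = 0.373) but passed without osteosarcoma 2 (adjusted p = 0.0357). Wnt genes were higher in 3 of 9 cases (3 adjusted over the list alone, adjusted p = 0.161), with the antagonist Wif1 at 3.04 ± 0.36 (detected on 2 of 4 leiomyosarcomas).

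**Figure D4:**
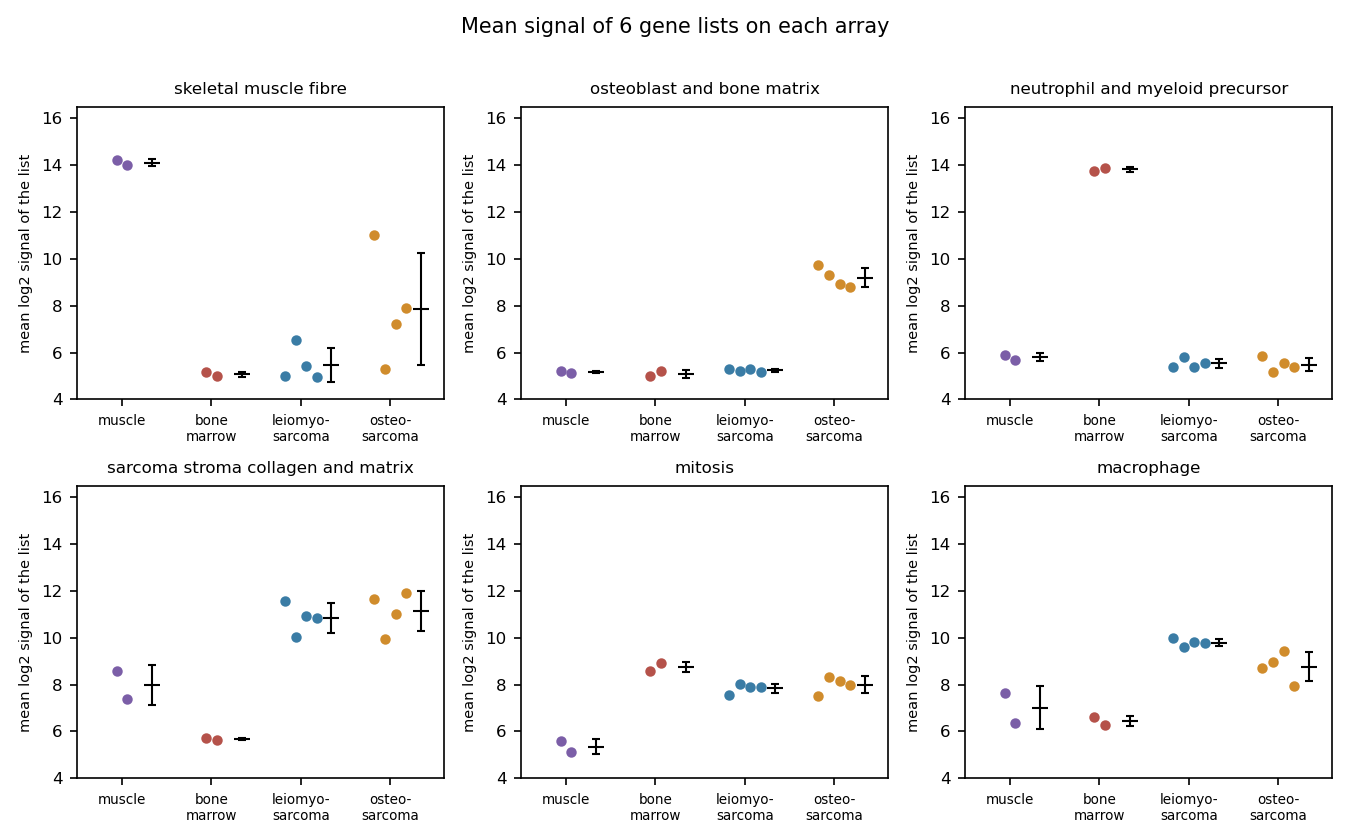
Mean log2 normalised signal (vertical axis) over the genes of 6 lists (skeletal muscle fibre, osteoblast, neutrophil, collagen, mitosis and macrophage) on each of the 12 arrays, 1 point per array, with the dash and bar giving the group mean ± SD of muscle (n = 2), bone marrow (n = 2), leiomyosarcoma (n = 4) and osteosarcoma (n = 4). Osteosarcoma 1 lies at 11.03 for skeletal muscle fibre genes, and the 4 osteosarcomas lie between 8.81 and 9.72 for osteoblast genes.

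Among the panel genes, Cdkn2a was lower in osteosarcoma (−1.42 ± 0.33, adjusted p = 0.0185), a call that ended with the background block (−1.14, adjusted p = 0.129), within the high-background arrays (adjusted p = 0.0773) and without osteosarcoma 1 (adjusted p = 0.0515). Cdkn1a (0.97 ± 0.77, adjusted p = 0.474), Mdm2 (0.46 ± 0.22, adjusted p = 0.203), Ccng1 (0.20 ± 0.24, adjusted p = 0.668), Rb1 (0.41 ± 0.36, adjusted p = 0.519), Myc (−0.29 ± 0.21, adjusted p = 0.428, detected on 3 of 4 osteosarcomas) and Top2a (0.21 ± 0.37, adjusted p = 0.782) did not pass. With the background block 271 genes were higher and 413 lower, 556 of them among the 899 called without it. Of 46 called named genes 3 moved by over 1.5-fold with the block, among them Prl2c3 (−6.70). A fit to the 6 high-background arrays alone, which gives the same fold changes but estimates the spread from fewer samples, called 202 and 322. Of 28 lists 6 were called, 7 with the block and 1 with an estimated correlation.

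The last comparison asked which genes differed from both normal tissues in both tumour types. Matrix and matrix protease genes, and Cdkn2a on the probe used, rose on the mean of both tumours, and neutrophil genes fell. The neutrophil fall came from bone marrow, the only tissue where, as above, the list was high. With an estimated correlation the protease and neutrophil list calls held and the matrix list call ended. In all 4 contrasts of a tumour type with a normal tissue 457 genes passed as higher and 127 as lower. The mean contrast, unlike that count, also moves with genes of 1 normal tissue or of 1 tumour type alone. On the mean of both tumours (n = 8) minus the mean of both normal tissues (n = 4), Mmp13 rose by 6.87 ± 0.27 (SE; adjusted p = 1.7e-08), its probe detected on 3 of 4 normal arrays, while its other probes gave 0.99 to 2.91, so its size and rank are not exact. The probe used for Cdkn2a was detected on 0 of 4 normal arrays and all 8 tumours, and was at least 5.24-fold higher there (adjusted p = 4.0e-06). Rbm38, an RNA-binding protein induced by p53, changed by −3.60 ± 0.23, from 10.29 ± 0.12 (SD, n = 4) to 6.70 ± 0.46 (n = 8; adjusted p = 4.3e-07).

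After Mmp13 the rises named by fitted difference were in Col1a1 (6.501 ± 0.38), Sparc (6.22 ± 0.33), Tnc (6.13 ± 0.65), Ctsk (6.08 ± 0.65) and Serpinh1 (6.07 ± 0.29). Col1a1 was detected on 2 of 4 normal arrays (7.16 or 5.84 without muscle 1 or 2) and Ctsk on 3. The falls were in Lcn2 (−6.20 ± 0.29), the calprotectin subunit S100a8 (−5.50 ± 0.55), the alpha-tubulin Tuba8 (−5.14 ± 0.17), the acute phase protein Orm1 (−3.998 ± 0.25), Rbm38 and Gca, the calcium-binding protein grancalcin (−3.55 ± 0.20). Lcn2 was detected on 4 of 8 tumour arrays, and Tuba8 and Orm1 on 1 of 8. Of 16 collagen and matrix genes 15 rose, 15 adjusted over the list alone. Their median was 4.36 (adjusted p = 7.2e-09, and 0.171 with an estimated correlation). Of 13 matrix proteases and inhibitors 12 rose (12 adjusted over the list alone; median 2.83; adjusted p = 3.7e-08, kept at adjusted p = 0.0112 with an estimated correlation), with Mmp14 at 5.69 ± 0.34 and Timp1 at 5.30 ± 0.33, each detected on 3 of 4 normal arrays. Macrophage genes rose in 10 of 12 cases (10 adjusted over the list alone, median 2.53, adjusted p = 1.7e-05, and adjusted p = 0.202 with an estimated correlation), and receptor tyrosine kinases and ligands in 9 of 14 (9 adjusted over the list alone, median 1.58, adjusted p = 0.000355, and adjusted p = 0.0973 with an estimated correlation), with Pdgfra at 4.41 ± 0.53 (detected on 2 of 4 normal arrays). All 15 neutrophil genes fell (15 adjusted over the list alone; median −4.50; adjusted p = 5.7e-15, kept at adjusted p = 0.0112 with an estimated correlation).

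Other lists were called on the mean of both tumours. Skeletal muscle fibre genes fell in 16 of 19 cases (16 adjusted over the list alone, median −3.11, −3.74 without osteosarcoma 1, adjusted p = 1.9e-05, and adjusted p = 0.383 with an estimated correlation), oxidative phosphorylation genes in 4 of 15 (4 adjusted over the list alone, median −0.87, adjusted p = 0.00146, and adjusted p = 0.383 with an estimated correlation) and erythroid genes in 5 of 8 (5 adjusted over the list alone, median −1.58, adjusted p = 0.00359, and adjusted p = 0.202 with an estimated correlation). Osteoblast genes rose in 9 of 13 cases (9 adjusted over the list alone, median 2.46, adjusted p = 0.00069, and adjusted p = 0.16 with an estimated correlation), endothelial genes rose in 6 and fell in 1 of 12 (7 called adjusted over the list alone, median 1.12, adjusted p = 0.0118, and adjusted p = 0.427 with an estimated correlation) and mitosis genes rose in 6 of 14 (6 adjusted over the list alone, median 0.64, adjusted p = 0.00563, and adjusted p = 0.383 with an estimated correlation). DNA replication genes rose in 3 of 16 cases, 3 adjusted over the list alone, not called as a list with the background block (adjusted p = 0.0814). This list was called at adjusted p = 0.00837, and had 0.401 with an estimated correlation. Wnt genes rose in 5 of 9 cases (5 adjusted over the list alone, adjusted p = 0.021, and adjusted p = 0.163 with an estimated correlation) and ribosomal protein genes in 1 of 11 (1 adjusted over the list alone, adjusted p = 0.00116, and adjusted p = 0.175 with an estimated correlation), neither called with median scaling (adjusted p = 0.0696 and 0.0522). Calls of 5 further lists ended without single samples. The interferon list (6 of 9 up, adjusted p = 0.021, and adjusted p = 0.427 with an estimated correlation) ended without muscle 2 (0.063) and with the block (0.12). The myogenic list (3 of 10 down, adjusted p = 0.0365, and adjusted p = 0.453 with an estimated correlation) ended without muscle 2 (0.16) or bone marrow 1 (0.0537) and with the block (0.0707). The adipocyte list (2 of 6 down, adjusted p = 0.026, and adjusted p = 0.175 with an estimated correlation) ended without muscle 2 (0.0549) and with the block (0.0752). The B lymphoid list (4 of 8 down, adjusted p = 0.032, and adjusted p = 0.408 with an estimated correlation) ended without bone marrow 1 (0.0571), muscle 1 (0.05) or muscle 2 (0.0513). The T and NK lymphoid list (2 of 8 down, adjusted p = 0.032, and adjusted p = 0.383 with an estimated correlation) ended without bone marrow 1 (0.0743) or muscle 2 (0.061) and with the block (0.1).

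Among the panel genes Ccng1 fell by 2.17 ± 0.21 (adjusted p = 1.0e-05), Rb1 by 1.73 ± 0.31 (adjusted p = 0.000773, and 0.0538 with the background block) and Top2a rose by 1.60 ± 0.32 (adjusted p = 0.00162, and 0.112 with the background block; detected on 2 of 4 normal arrays). Mdm2 changed by −0.95 ± 0.19 (adjusted p = 0.00146), under the fold minimum, and Cdkn1a (−0.45 ± 0.66, adjusted p = 0.597) and Myc (0.40 ± 0.18, adjusted p = 0.0885, detected on 7 of 8 tumours and 2 of 4 normal arrays) did not pass. Of 17 p53 target genes 4 fell (4 adjusted over the list alone, adjusted p = 0.186), with Gadd45a, a growth arrest gene, at −3.18 ± 0.68 (−4.18 or −2.18 without muscle 1 or 2, whose levels were 9.04 and 13.04). The effect of a tumour against its normal tissue differed between the bone and muscle sides in 4733 genes of the limma interaction, 2289 with a higher and 2444 with a lower effect on the bone side. Between leiomyosarcoma against muscle and osteosarcoma against bone marrow, which share no samples, 643 genes were higher in both and 164 lower in both, against 350.1 and 231.1 for independent lists, while 430 were higher in the first and lower in the second, against 306.5, and 258 the reverse, against 264.

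In 20 limma simulations of unchanged groups 0 genes passed all 4 contrasts. With the background block 309 genes were higher and 68 lower in all 4, and 16 lists were called against 19 without it. Of 100 called named genes 19 moved by over 1.5-fold with the block, among them Rbm38 (−2.97) and Mmp14 (6.32). The block ended 5 of these calls and added the chondrocyte and oncofetal lists (adjusted p = 0.0295 and 0.0252). The share of higher genes depended on the scaling. Of the genes called on the mean of both tumours 58.8% were higher, 82.5% with median scaling, 90.4% on the authors' unsubtracted signals and 43.3% with median scaling over detected probes. The corresponding shares were 57.0%, 80.7%, 85.0% and 42.7% for leiomyosarcoma against muscle and 53.3%, 72.7%, 81.0% and 44.9% for osteosarcoma against bone marrow. These scalings moved the median of all genes from 0.00162 to 0.426, 0.489 and −0.262 in the mean comparison, from 0.077 to 0.529, 0.532 and −0.31 in the first and from 0.0273 to 0.337, 0.476 and −0.2 in the second, so changes are relative to that median.

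List tests, medians and means differed in sign only in lists that were not called. In leiomyosarcoma against muscle these were osteoblast genes (median 0.03 and mean 0.07, tested lower), osteoclast genes (median −0.06, mean 0.72, tested higher), erythroid genes (median −0.08, mean 0.14, tested lower), glycolysis (median −0.53, mean 0.03, tested lower) and sex-linked genes (median 0.08, mean −0.64, tested lower). In osteosarcoma against bone marrow they were p53 targets (median −0.04, mean 0.24, tested higher), handling genes (median 0.13, mean −0.28, tested lower) and sex-linked genes (median −0.37, mean 1.22, tested lower). In osteosarcoma against leiomyosarcoma they were neutrophil genes (median 0.06, mean −0.04, tested higher), collagen and matrix genes (median −0.06, mean 0.29, tested higher) and sex-linked genes (median −0.21, mean 1.27, tested lower). On the mean of both tumours they were the sex-linked genes alone (median −0.11, mean 0.29, tested lower).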

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

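The tests in this part were planned, except the values with the background level as a block and the panel differences without single samples, which were chosen after the data were seen.

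Single samples lay far from the others of their group in 8 of 150 tests, where chance gives about 1 in 20 (7.5 expected). The gap to the nearest sample, as a share of the group range, was 0.834 for Rb1 in leiomyosarcoma 4, which was lowest. It was 0.924 for the surface receptor gene Scarf2 in leiomyosarcoma 1, highest, and 0.836 for the Wnt list in leiomyosarcoma 4, lowest. Among osteosarcomas it was 0.835 for Mdm2 (osteosarcoma 4, highest), 0.917 for Ltf (osteosarcoma 1, highest), 0.858 for Ibsp (osteosarcoma 2, lowest), 0.882 for Sp7 (osteosarcoma 4, lowest) and 0.988 for Tuba8 (osteosarcoma 1, highest).

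As above, the tumour effect differed between the bone side and the muscle side in 4733 genes of the limma interaction. Among the panel genes the difference, bone side minus muscle side, was 4.2246 log2 for Ccng1 (adjusted p = 1.3e-05), 3.8429 for Cdkn1a (adjusted p = 0.0353) and −3.9925 for Top2a (adjusted p = 0.000375). The 2 muscles differ in Cdkn1a by 4.39 log2, and its difference was 1.6445 (adjusted p = 0.164) without muscle 2 and 6.0412 without muscle 1. Its call held without muscle 1, osteosarcoma 2 or osteosarcoma 4 and ended without any other single sample (adjusted p from 0.0505), while Ccng1 and Top2a kept theirs without each sample. With bone marrow and muscle as different kinds of tissue, a difference of this sort also holds every gene that differs between the normal tissues.

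For 15 lists the difference between the sides was called. The medians were 12.4046 for skeletal muscle fibre genes, 6.3252 for myogenic genes, 4.7221 for osteoblast genes, 2.9961 for collagen and matrix genes, 2.5224 for oxidative phosphorylation, 2.1705 for endothelial genes, 1.4696 for adipocyte genes and 0.8412 for smooth muscle genes. They were −8.7536 for neutrophil genes, −3.6089 for mitosis, −3.59 for DNA replication, −3.4115 for erythroid genes, −2.2669 for B lymphoid genes, −1.6097 for T and NK lymphoid genes and −0.7285 for ribosomal protein genes. Only the neutrophil list was called with an estimated correlation (adjusted p = 0.0193). The smooth muscle call (adjusted p = 0.0474) ended with the background block (adjusted p = 0.0595).

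The number of genes that differ between the tumour types was compared with other splits of the 8 tumours into 4 and 4. Of 35 splits the real one gave 899 genes and the highest other 3. The others mix tumour types within groups, so chance is not excluded. Genes that differ from both normal tissues in both tumour types were compared with 100 regroupings of the 12 samples, the real one included. Only the real one called as many as 584, and the highest other called 0. These regroupings also mix tissues within groups, so chance is not excluded there either.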

How the results depend on the processing

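The background block, the sets by background level and median scaling over detected probes were chosen after the data were seen, and the other alternatives were planned. Of 339 calls of named genes, 336 kept their direction in every alternative run and 205 kept direction and call. The planned slide block was not run, as the files name no slide. Where a replicate was left out of a group of 2, the lone sample was assumed to vary like the other groups. Signals near the background limit the folds of dim genes. Causes of the changes below were not tested.

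With no background correction 1517 genes were higher in leiomyosarcoma than in muscle, 1131 were higher and 998 lower in osteosarcoma than in bone marrow, 213 higher and 295 lower in osteosarcoma than in leiomyosarcoma, and 285 higher and 55 lower in both tumours. An offset of 50 gave 77 lower in both tumours. Median scaling gave 3938 and 945 in leiomyosarcoma against muscle, 2619 and 983 in osteosarcoma against bone marrow, and 973 and 32 in both tumours. The authors' unsubtracted signals gave 596 and 576 lower genes in the first 2 comparisons, 198 higher and 266 lower between the tumours, 864 and 10 in both tumours, and 3082 in the interaction. No minimum fold gave 629 and 799 between the tumours and 287 lower in both. The background block gave 1105 higher genes in osteosarcoma than in bone marrow and 68 lower in both tumours. Within the high-background arrays 202 and 322 genes differed between the tumours. An estimated correlation left 0, 2, 1 and 2 lists called in the 4 comparisons.

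Of called genes, Elane (0.0622) and Lep (0.0793) in leiomyosarcoma against muscle changed sign on the authors' signals, and Vwf on the mean of both tumours (0.1936) with the background block. Signs of uncalled panel values also turned. In osteosarcoma against bone marrow, Ccng1 was 0.4574 with median scaling, 0.5696 on the authors' signals, 0.0293 with array weights, and 0.0514, 0.0177 and 0.0621 without bone marrow 1, osteosarcoma 2 or osteosarcoma 3 (range with each sample left out −0.2319 to 0.0621). Top2a was 0.0788 with median scaling and 0.2786 on the authors' signals. Myc was −0.1996 with median scaling over detected probes, −0.036 with array weights, and −0.0029, −0.0734 and −0.0438 without the same 3 samples (range to 0.1708). On the mean of both tumours Cdkn1a was 0.0379 with median scaling, 0.1346 on the authors' signals and 0.6464 without muscle 2 (range from −1.552), and Myc −0.0212 with median scaling over detected probes. Between the tumours Top2a was −0.0628 with array weights, −0.0817 without osteosarcoma 2 (range to 0.4992) and −0.0576 both with the background block and within the high-background arrays, where Ccng1 was −0.1183 in both.

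Leaving out each sample gave 2092 to 2426 higher and 1701 to 1793 lower genes in leiomyosarcoma against muscle. The ranges were 1254 to 1870 and 1242 to 1569 in osteosarcoma against bone marrow, 289 to 473 and 385 to 532 between the tumours, 355 to 503 and 93 to 133 in both tumours, and 3911 to 4817 in the interaction. Lists called ranged over 11 to 12, 15 to 20, 6 to 7 and 14 to 22. Muscle 2 gave the lowest gene counts of the first comparison, bone marrow 2 those of the second, of both tumours and of the interaction, and leiomyosarcoma 3 those between the tumours. Over 14 pairs of equal replicate number, deviations from group means correlated at −0.0786 to 0.0819, so they were not treated as pairs. In the same 4 comparisons the replicate block gave 2233 and 1684, 1634 and 1443, 381 and 492, and 435 and 110 genes. Without both samples that share an animal code the counts were 1985 and 1717, 1264 and 1275, 332 and 452, and 324 and 101.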

Other observations

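Tests of the neighbouring gene scan, of Xist and of tumour cells in muscle 2 were chosen after the results were seen, and the genes named in this part were chosen after their values were seen.

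Il1b, the cytokine interleukin 1 beta, stood at 8.51 ± 0.50 (SD, n = 4) in leiomyosarcoma against 5.36 ± 0.48 (n = 4) in osteosarcoma (−3.15 ± 0.31 (SE), adjusted p = 0.0001), and at 9.84 ± 0.66 (n = 2) in bone marrow. The chemokine genes Cxcl1 (−3.59 ± 0.51), Ccl2 (−3.30 ± 0.47) and Ccl7 (−3.19 ± 0.62) were lower in osteosarcoma than in leiomyosarcoma too, as were the lymphatic growth factor gene Vegfc (−3.29 ± 0.50) and the BMP antagonist gene Grem1 (−3.69 ± 0.23, adjusted p = 2.3e-06). All 6 rose from muscle to leiomyosarcoma, from 3.50 for Il1b to 4.33 for Ccl7. None was called between osteosarcoma and muscle, where Ccl7 differed by 1.14 (adjusted p = 0.248) and Il1b by 0.35 (adjusted p = 0.495).

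Of 22 measured Hox genes, the homeobox genes of body position, 4 were higher and 3 lower in osteosarcoma than in leiomyosarcoma, 15 were not called, and they were not tested as a set. Hoxc6 was lower in osteosarcoma (8.63 ± 0.45, n = 4) than in leiomyosarcoma (11.63 ± 0.13, n = 4; −3.01 ± 0.28, adjusted p = 6.6e-05), as were Hoxd8 (−2.37 ± 0.33) and Hoxd4 (−1.19 ± 0.28). Hoxa5 (2.31 ± 0.40), Hoxa7 (1.91 ± 0.40), Hoxb2 (2.35 ± 0.34) and Hoxb4 (1.0001, adjusted p = 0.0426) were higher. Smooth muscle actin, Acta2, stood at 13.28 ± 1.15 in leiomyosarcoma and 13.26 ± 1.47 in osteosarcoma (−0.02, adjusted p = 0.989) and at 11.88 ± 0.73 (n = 2) in muscle, from which neither tumour was called different (adjusted p = 0.201 and 0.215). On the mean of both tumours Acta2 rose by 1.68 (adjusted p = 0.0398), a call that ended with the background block (0.52, adjusted p = 0.717). The smooth muscle genes Cnn1 (4.93 ± 0.06) and Myocd stayed near background in leiomyosarcoma.

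Muscle 2 exceeded muscle 1 by 23.3-fold in Myog, 4.79-fold in Myod1 and 21-fold in Cdkn1a. A candidate explanation is denervation of that muscle, for which a list of 10 further genes was written after those 3 had been seen and before the values of the list were looked up. The 10 genes had a median difference of 3.1627 log2, above all 10000 lists of matched level (95th percentile 0.3739), with 8 of 10 over 1 log2, among them Chrng (25.7-fold), Runx1 (17.4-fold) and Ankrd1 (73.8-fold). Of these 10 genes, 3 (Chrna1, Chrng and Gadd45a) are also in the planned lists. Against osteosarcoma or leiomyosarcoma cells in that muscle, the 50 genes with the largest excess of osteosarcoma over muscle 1 differed by a median of −0.0314, 3 of 50 over 1 log2, and those of leiomyosarcoma by 0.0728, 5 of 50 over 1 log2, while the handling and stress list was also higher in muscle 2 (8.27 against 6.99), and handling, regeneration and injury were not tested and the comparison is of 1 sample with 1.

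Xist was detected with 4 of 4 probes on all 4 osteosarcomas and on muscle 2, and with 0 on the other 7 arrays. The background level does not account for it, as osteosarcoma exceeded leiomyosarcoma by 6.1518 log2 within the high-background arrays, against 6.21 over all tumours. Animals of different sex may account for it, but 5 of the 7 arrays with low Xist detected any Y-linked probe, as did 3 of the 5 with high Xist. Of the 8 Y-linked probes, all near background, 4 low-Xist arrays detected 2 or 3 and high-Xist arrays at most 1. This goes with a sex difference, but 2 low-Xist arrays detected 0. Tumour type cannot explain Xist in muscle 2, but among tumours sex and type cannot be told apart.

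Yap1, a growth-promoting coactivator, was 66.4-fold and Birc2, an apoptosis inhibitor, 23.8-fold higher in osteosarcoma 2 than the median of the other osteosarcomas, both looked up from knowledge of mouse tumours. On that array 0.0426% of genes rose as far as Birc2, but its array weight was the lowest (0.5445), so an outlier is not excluded. The planned test of the 11 other genes within 5 positions gave a median of 0.1269 log2. This lay under the 95th percentile of random runs (0.397), so a joint rise was not shown. Of the 11, 4 lay under the lowest detected signal in the other osteosarcomas. Set as high as any, these bring the median to 0.5081. Of these 4, Birc3 (10.6-fold) and Mmp10 (8.77-fold) were high. A later scan of 7-gene windows along GRCm38.p6 found 3 runs in this sample, the highest at 3.5686 log2 (limit over random gene orders 1.2671), 1 of them with Dync2h1, Dcun1d5, Birc2, Birc3 and Yap1 and 1 with Pdgfra (6.91-fold), with 8 of 11, 10 of 16 and 7 of 13 genes over 1 log2 in the 3 runs and Kit (0.564-fold) not raised, among 10 runs in 5 of 8 tumours that also held histone, chemokine and histocompatibility gene clusters. Gains of DNA copies in that tumour may underlie these runs, a hypothesis that RNA levels alone leave untested.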
